A study of Bos taurus with 6 samples.

How the data were processed

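RNA sequencing was used to measure transcripts in bovine blastocysts produced in vitro. The 6 libraries came from embryos with high cryosurvival after vitrification (3 libraries) and embryos with low cryosurvival (3 libraries), and were grouped by the cryosurvival stated in their labels. The sample titles also carry the codes V for every high and NV for every low cryosurvival library. The labels do not explain these codes, so a further difference between the groups that they may mark was not separated from cryosurvival here. Per the labels' protocols, total RNA was purified with a column kit and treated with DNase, every sample had an RNA integrity number of at least 7.7, and libraries were made with the NEBNext Ultra II RNA kit. The labels do not say whether the 3 libraries of a group came from separate cultures or pools. The p-values per gene therefore measure only the spread between these samples, which may be technical. TopHat2 2.0.8, Bowtie2 2.1.0, Cufflinks 2.1.1, SAMtools 0.1.18, HTSeq 0.5.4p2 and DESeq 1.12.1 are named by the submitters' processing notes, without a role for any of them. The genome build, the annotation, the use of strand and the filter on low genes are not given in the sources used here, so no coordinates are reported. Without stated strand use, reads of a gene and of an overlapping or antisense gene were not told apart here.

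The authors' deposited table held 9537 genes by name, with a value per gene and library, a log2 fold, a p-value and an adjusted p-value. The values per library were CPM (read counts scaled to a fixed library size) with 3 decimals. This unit was worked out from the values. The values of up to 1000 CPM were whole multiples of 1 step per library, within 0.05 read, for 100% of the values checked, against 10% for random values. The reads recovered in this way summed to 17591314, 18987154 and 17807574 in high cryosurvival libraries 1, 2 and 3. They summed to 19467022, 14651477 and 18349282 in low cryosurvival libraries 1, 2 and 3. The reads in the table divided by the scaled library size came to between 0.961 and 0.996 in 5 libraries and to 1.1 in low cryosurvival library 2. The lowest mean over the 6 libraries was 0.737 CPM, so genes below this level were not analysed here. The deposited log2 fold is high over low cryosurvival; its sign was turned to low over high here. Which tool made the deposited p-values is not given in the sources used here, and these p-values carry 3 decimals. Of the gene names, 9007 were a symbol and 474 a synonym in the gene table of assembly ARS-UCD2.0, and 56 had no match there.

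The 2 groups were compared with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with all 6 libraries, no covariate and Benjamini-Hochberg adjustment over all genes, at an adjusted p of 0.05. Differences are low minus high cryosurvival, and with a pseudocount of 1 they understate the change of genes at low CPM. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so no such test was made per gene. Gene lists were tested with camera from limma, at a preset correlation between genes of 0.01 and again with an estimated correlation. At the preset correlation camera judges a list against the spread between genes, so these p-values do not measure the spread between libraries. Both were also run with a length index as covariate and without low cryosurvival library 2, the estimated correlation there as a choice made after the values were seen. Of 25 lists, 22 had at least 5 measured members and were tested. The oocyte and maternal list had 3, the sperm list 4 and the mitochondrial genome list 0. Fisher's exact test on the authors' deposited calls, chosen after the values were seen, treats genes as independent. Its p-values do not measure the spread between libraries either. A list's median was also placed among the medians of 10000 random lists of equal size matched on mean expression in 10 bins. The design, the lists, some of the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per direction, the 12 called genes with the largest fold, the 3 called genes with the highest expression, up to 4 called members per list and the 2 highest expressed members of each list without a called member; some genes the rule selects are not reported here. Because limma called no gene, the rule was applied to the calls of the authors' deposited table, a change made after the values were seen. As applied, it also took the 2 highest expressed members of the lists that had a called member.

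An additional limma model had a length index as covariate. The index of a library is the median log2(CPM + 1) of 35 measured genes with long messenger RNAs minus that of 52 measured genes with short ones, both sets written from general knowledge of these genes. This model leaves 3 residual degrees of freedom, and it was chosen after the test without covariate had given 0 calls. The index comes from the same expression values. Within the groups it varies mainly through low cryosurvival library 2 (-1.63, against 0.65 and 0.23 in low libraries 1 and 3). The slope of each gene is thus set mainly by that library, so its deviation adds little to the residual spread. Its value still enters the group difference. The log2 difference of MGC148328 was 1.71 with all libraries, 1.60 with the index and 1.27 without low library 2. Other alternatives covered thresholds, a pseudocount of 0.1, a filter on low genes, scaling, a replicate block and leaving out each library. Chosen only after the result was seen were a pseudocount of 0.5, libraries centred on their medians, an intensity trend, a weight per library and voom on the recovered reads. On simulated data with the spread of all 6 libraries and 9537 genes, limma recovered 53% of genes changed 2-fold and 91% of genes changed 4-fold between low and high cryosurvival, and 2% of its calls were false. With the spread of the 3 high cryosurvival libraries it recovered 86% and 100%, and 7.5% of its calls were false. Each figure comes from a single simulated set, with changed genes taken only from those with a mean above 5 CPM. Genes were drawn independently, without the deviation that low cryosurvival library 2 shares across genes. These rates therefore do not describe the test on the real libraries. Percentiles and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.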

Results

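The transcriptomes of bovine blastocysts produced in vitro were compared between embryos of high and of low cryosurvival, that is, survival after vitrification, an ice-free form of rapid freezing. Each group had 3 libraries, with 14651477 to 19467022 reads in the table per library. The 9537 genes measured are given in CPM of a scaled library size. The comparison addressed which transcripts separate embryos that differ in cryotolerance. Whether RNA was taken before or after vitrification is not given here, so the differences are not placed before or after it.

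In the calls of the authors' deposited table, low cryosurvival embryos had higher levels of the chaperone HSPA5, the adhesion molecule ICAM1, the NF-kappaB subunit NFKB2 and the p53 target CDKN1A. High cryosurvival embryos had higher levels of the pluripotency factor NANOG, the NODAL antagonist LEFTY2 and the angiogenic factor VEGFA in the authors' deposited table. The authors' deposited table held 114 genes with an adjusted p below 0.05, and 87 of them were higher in low cryosurvival embryos and 27 higher in high cryosurvival embryos. The share higher in low in the authors' deposited table was 76.3%. In all 114 genes of the authors' deposited table the 3 libraries of one group lay above the 3 of the other. Of all genes, 21% had this property, against 10% by chance. The limma test without covariate called 0 genes at an adjusted p of 0.05, with 1142 genes at an unadjusted p below 0.05 against 477 by chance, and voom on the recovered reads also called 0. Of the 1142 genes, 598 were higher and 544 lower in low. Splits of the libraries that mixed the groups gave 52 to 1319 such genes, so the excess over 477 does not by itself mark a group difference. The genes of the authors' deposited table had limma adjusted p values from 0.0519 to 0.302. Library 2 of the low cryosurvival group decided the count of genes called by limma. Without it limma called 1300 genes, 777 higher and 523 lower in low. With the length index as covariate, a model chosen after the test without covariate had given 0 calls, limma called 1092 genes, 598 higher and 494 lower in low cryosurvival. They included 113 of the 114 genes of the authors' deposited table. Those genes were selected on these same libraries, so neither this overlap nor their separation by library is independent support for them. The model with the length index takes most of the deviation of low cryosurvival library 2 out of the spread, while its value stays in the group difference. Its calls and those made without that library share the remaining libraries and are not independent results.

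Among the genes with the largest folds, TNFRSF9, a costimulatory receptor of the tumour necrosis factor receptor family, was at 3.69 ± 0.338 CPM in low and 0.814 ± 0.219 CPM in high cryosurvival embryos (SD, n = 3 each). Its limma adjusted p was 0.0519, and 0.00694 with the length index. The gap junction gene GJB2 was at 1.37 ± 0.156 against 0.273 ± 0.00964 CPM, and the cytokine receptor chain IL2RG at 2.24 ± 0.245 against 0.641 ± 0.208 CPM. Their limma adjusted p values were 0.0868 and 0.125, and 0.0085 and 0.0104 with the length index. The high mean of GJB2 rests on few reads, as 1 read equalled 0.0524 to 0.0560 CPM in the high libraries. Its SD there is below the spread that counting reads alone gives. The high means of KRT6A, MGC148328, LRRC8C, MAG and MMP1, given next, also rest on few reads. KRT6A, a keratin of stressed epithelia with close paralogs that may share its reads, was at 3.64 ± 1.58 against 0.522 ± 0.283 CPM, a ratio of 6.97. MGC148328 had the largest fold in the authors' deposited table, 3.56 on the log2 scale, and its limma adjusted p was 0.192. Its mean was 3.78 CPM in low and 0.312 CPM in high cryosurvival embryos. Low cryosurvival library 2 was the highest, at 6.8 CPM against 3.1 and 1.4 CPM in low libraries 1 and 3. The limma log2 difference of MGC148328 was 1.71, and 1.27 without low library 2. Other genes of this rank were LRRC8C, a subunit of volume-regulated anion channels, with a low over high ratio of 5.76, MAG (3.65), CRCT1 (3.61), PCDH8 (3.59), the collagenase MMP1 (3.57), SPOCK1 (3.51) and IGFBP6 (3.48). All of these genes were called by limma with the length index, with adjusted p values from 0.00694 for TNFRSF9 to 0.027 for MAG. CRCT1 leaned on low cryosurvival library 2, at 31.5 CPM against 10.3 and 12.1 CPM in low libraries 1 and 3. Its limma log2 difference was 1.55, and 1.08 without that library. The most highly expressed genes of this direction were HSPA5, PLAU, which encodes urokinase, and MFGE8. PLAU was at 842 ± 172 against 462 ± 79.5 CPM and MFGE8 at 727 ± 95.8 against 425 ± 41.3 CPM. Limma gave adjusted p values of 0.192 and 0.164, and of 0.0171 and 0.0194 with the length index.

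In the other direction, NANOG was at 38.7 ± 8.15 CPM in high and 16.2 ± 5.20 CPM in low cryosurvival embryos, and LEFTY2 at 8.18 ± 2.47 against 2.80 ± 1.20 CPM (SD, n = 3 each). The limma adjusted p values were 0.164 and 0.176, and 0.0187 and 0.0129 with the length index. The potassium channel gene KCNH6 was at 14.9 ± 0.552 against 6.20 ± 0.427 CPM, and DQX1, a helicase-like gene, at 32.5 ± 4.27 against 11.8 ± 1.28 CPM (limma adjusted p = 0.0519 for both). VEGFA was at 105 ± 6.96 CPM in high and 55.9 ± 14.5 CPM in low cryosurvival embryos. OSBPL7 and ZNF131, also among the most highly expressed of this direction, had high over low ratios of 1.81 and 1.68. The kinase gene NIM1K had the largest ratio, 4.34, at 1.39 ± 0.0730 against 0.319 ± 0.149 CPM. Its mean in low cryosurvival embryos rests on few reads, as 1 read equalled 0.0499 to 0.0751 CPM in the low libraries. LEFTY2 (2.93), ZCWPW1 (2.78), DQX1 (2.75), NREP (2.65), FREM1 (2.56), MYH1 (2.53), ZNF135 (2.53), KCNH6 (2.40), NANOG (2.39), MYH3 (2.37) and LOXL3 (2.25) followed in the ratio of high over low cryosurvival. Limma called each of these genes when the length index was in the model, with adjusted p values from 0.00694 for KCNH6 to 0.0442 for NREP.

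**Figure D1:**
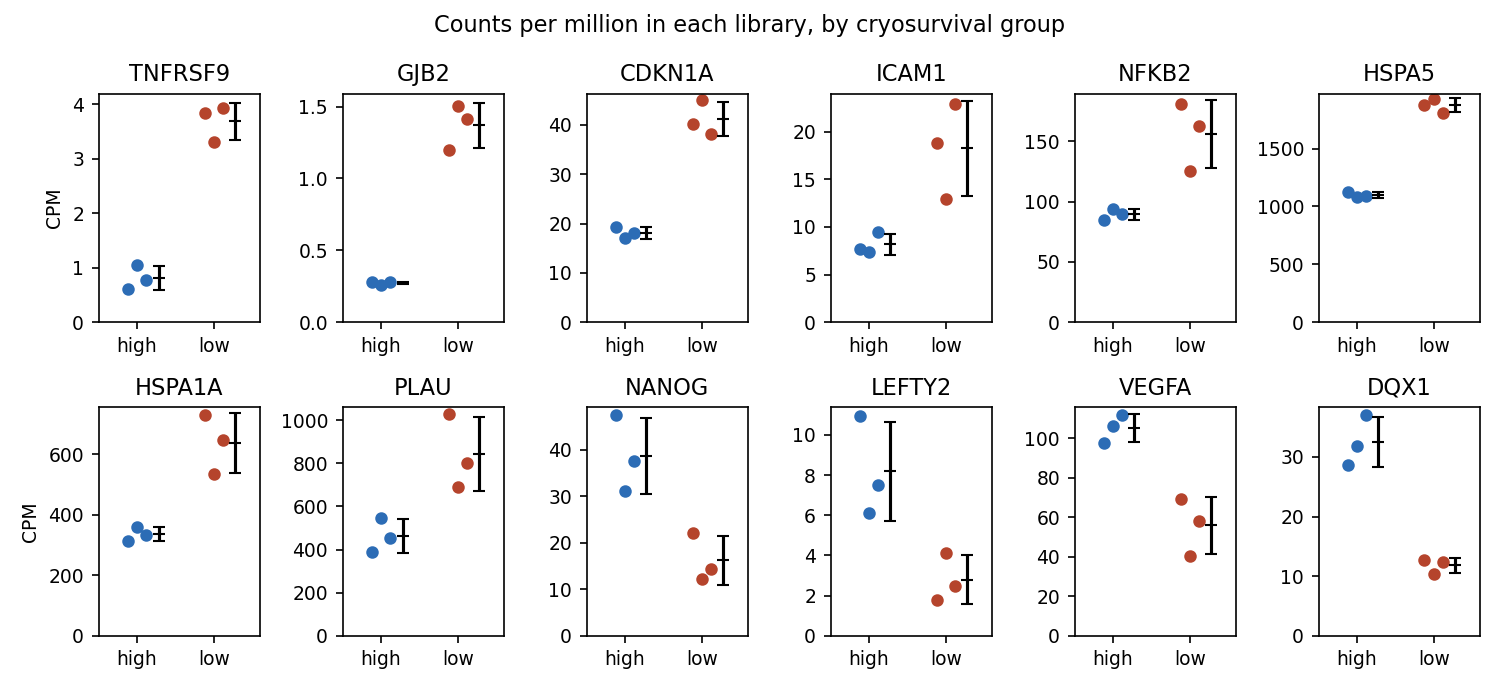
Points are the CPM of each of the 6 libraries for 12 genes, high cryosurvival in blue and low cryosurvival in red; the horizontal tick and bar beside them are the mean and SD of 3 libraries. The first 8 genes were higher in all 3 low libraries, and NANOG, LEFTY2, VEGFA and DQX1 were higher in all 3 high libraries.

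Genes of the heat shock and unfolded protein response were higher in low cryosurvival embryos as a group. The list of 33 measured genes had a median log2 difference of 0.27, with 25 members higher and 8 lower (camera adjusted p = 2.38e-05; adjusted p = 0.169 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, was at 1872 ± 60.4 CPM in low and 1099 ± 25.5 CPM in high cryosurvival embryos. HSPA1A, an inducible cytosolic chaperone with a near-identical copy, was at 637 ± 98.0 against 336 ± 23.3 CPM and its cofactor BAG3 at 90.3 ± 16.6 against 51.1 ± 3.24 CPM (SD, n = 3 each). These 3 genes were called in the authors' deposited table, at adjusted p values of 0.015, 0.003 and 0.02, and they were the only called members there (Fisher's exact test of the list, adjusted p = 0.0722). By limma 0 members passed over all genes and 8 passed when adjusted over the list alone, 7 higher and 1 lower in low. The lower one was HSPA2, named after its value was seen, as were the genes HSP90B1, DNAJB9, DNAJB1 and PDIA4 among the higher ones. Of the 33 members, 11 were called with the length index, 10 higher and 1 lower, and 22 did not pass. In that model 20 passed when adjusted over the list alone. Without low cryosurvival library 1 the median of the list was 0.18. HSPA8 and HSP90AB1, the most abundant members, were at 4153 ± 452 against 3856 ± 103 CPM and 3018 ± 486 against 2475 ± 133 CPM. Neither was called in either model.

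Inflammatory and cytokine genes were higher in low cryosurvival embryos in 16 of 17 measured members, with a median log2 difference of 0.27 (camera adjusted p = 0.000124; adjusted p = 0.169 with an estimated correlation). ICAM1, an adhesion molecule induced by cytokines, was at 18.2 ± 4.97 CPM in low and 8.18 ± 1.09 CPM in high cryosurvival embryos (SD, n = 3 each). NFKB2 was at 156 ± 28.4 against 89.6 ± 4.48 CPM and the cytokine signalling inhibitor SOCS3 at 8.72 ± 0.807 against 4.13 ± 1.1 CPM. In the authors' deposited table these 3 genes had adjusted p values of 0.01, 0.02 and 0.046 (Fisher's exact test of the list, adjusted p = 0.02). By limma 0 members passed over all genes and 4 passed adjusted over the list alone, each higher in low. These were ICAM1, NFKB2, SOCS3 and the interleukin gene IL1A, the last named after its value was seen. In the model with the length index 6 were called, each higher in low, and 8 passed adjusted over the list alone. PTGS2, the most abundant member and also on the trophectoderm list, was at 1083 ± 141 against 1032 ± 89.3 CPM and was not called. The 18 measured interferon-stimulated genes had a median log2 difference of -0.07 and no called member (camera adjusted p = 0.645). Without high cryosurvival library 2 this list was called lower in low (camera adjusted p = 0.00462), and without high library 1 its median was 0.08 (0.968).

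The apoptosis and p53 list was also higher in low cryosurvival embryos, with 21 of 30 measured members higher and a median log2 difference of 0.19 (camera adjusted p = 0.00712; adjusted p = 0.169 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21 and a p53 target, was at 41.2 ± 3.45 CPM in low and 18.1 ± 1.14 CPM in high cryosurvival embryos (SD, n = 3 each). Its limma adjusted p was 0.0519, and 0.00694 with the length index. Without covariate 0 members passed over all genes, and CDKN1A was the only one to pass adjusted over the list alone. The model with the length index called 4 members higher and 2 lower in low, and 11 of the 30 passed adjusted over the list alone. Oxidative stress genes had a median log2 difference of 0.20, with 23 of 34 measured members higher (camera adjusted p = 0.0373; adjusted p = 0.668 with an estimated correlation). By limma 0 passed over all genes or adjusted over the list alone. Low cryosurvival library 2 decided this list. Without it the median was 0.09 and the camera adjusted p 0.931. The call was also lost without high cryosurvival library 3 (adjusted p = 0.0718) and with the length index (0.0846). PRDX1 and PRDX2, its most abundant members, were at 1836 ± 725 against 1779 ± 245 CPM and 1392 ± 494 against 1393 ± 83.8 CPM.

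Among markers of the cell lineages of the blastocyst, hypoblast genes were higher in low cryosurvival embryos, with 10 of 14 measured members higher and a median log2 difference of 0.48 (camera adjusted p = 0.0319; adjusted p = 0.502 with an estimated correlation). Low cryosurvival library 2 did not share this to the same extent: its hypoblast median was 0.10 above the high mean, at the 69.2th percentile of random lists, against 0.51 and 0.32 in low libraries 1 and 3. The hypoblast call was lost without low cryosurvival library 1 (camera adjusted p = 0.209, median 0.40) and without high library 3 (0.0826, median 0.27). By limma 0 hypoblast members passed over all genes and 2 passed adjusted over the list alone, both higher in low. These were RSPO3 and BMP2, secreted signals named after their values were seen. The model with the length index called 4 members, each higher in low. The most abundant hypoblast members, FN1 and COL4A1, were at 2079 ± 728 against 2173 ± 328 CPM and 303 ± 113 against 202 ± 31.5 CPM. The log2 difference of FN1 was -0.13 and turned to 0.21 without low cryosurvival library 2, with neither called. Trophectoderm markers had a median log2 difference of -0.12 (camera adjusted p = 0.214) and 0 members past limma over all genes or adjusted over the list alone. KRT8 was at 18190 ± 3271 against 18210 ± 1044 CPM and KRT18 at 11190 ± 1845 against 13200 ± 1410 CPM. Without low cryosurvival library 2 or without high library 1 the trophectoderm list was called lower in low (camera adjusted p = 0.02 and 0.0497; adjusted p = 0.593 with an estimated correlation without low library 2). The direction rested on single libraries, since the median was -0.05 without high library 2 and 0.06 without low library 3 (camera adjusted p = 0.497 and 0.929). With the length index 3 trophectoderm members were called lower in low, GATA2, DAB2 and TFAP2A, and 1 higher, the placental gene PAG11, which has close paralogs. These were named after their values were seen. Inner cell mass and epiblast markers had a median log2 difference of -0.07 (camera adjusted p = 0.352), which ranged from -0.25 to 0.04 with each library left out. NANOG was the only member to pass adjusted over the list alone. With the length index NANOG and, named after their values were seen, DNMT3B and DPPA3 were called lower in low and LIN28A higher. The DNMT3B value rested on low cryosurvival library 2, at 120 CPM against 378 and 326 CPM in low libraries 1 and 3, and its log2 difference by limma was -0.54 with this library and -0.03 without it (adjusted p = 0.721 and 0.886). POU5F1, the most abundant, was at 745 ± 166 CPM in low and 732 ± 39.9 CPM in high cryosurvival embryos, and its log2 difference of 0.004 became -0.17 without low library 2 (adjusted p = 0.996 and 0.296). The 11 measured cumulus and granulosa cell genes, markers of the cells that surround the oocyte, had a median log2 difference of -0.13 and a mean of 0.02 (camera adjusted p = 0.822), with HSD3B1 at 267 ± 37.4 against 307 ± 48.3 CPM.

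Cell junction genes were higher in low cryosurvival embryos in 29 of 37 measured members, with a median log2 difference of 0.13 (camera adjusted p = 0.0349; adjusted p = 0.668 with an estimated correlation). In low cryosurvival library 2 the junction list went the other way, with a median of -0.22 against the high mean. Without this library the median was 0.30 (camera adjusted p = 0.000132; adjusted p = 0.464 with an estimated correlation). The call was lost without low library 1, low library 3 or high library 3, with medians of 0.04, 0.08 and 0.06 (adjusted p = 0.357, 0.167 and 0.136). GJB2 was the only one to pass limma adjusted over the list alone, and 6 members were called with the length index, each higher in low. Genes of DNA methylation and chromatin enzymes were lower in low cryosurvival embryos in 18 of 22 measured members, with a median log2 difference of -0.17 (camera adjusted p = 0.0223; adjusted p = 0.502 with an estimated correlation). Without low cryosurvival library 2 this adjusted p was 0.327 and the median -0.04. DNMT3A, a de novo DNA methyltransferase, was at 788 ± 126 CPM in low and 1042 ± 101 CPM in high cryosurvival embryos. By limma 0 members passed adjusted over the list alone and 3 were called lower with the length index. Fatty acid beta-oxidation genes were lower in low cryosurvival embryos in 18 of 26 measured members, with a median log2 difference of -0.12 (camera adjusted p = 0.0373; adjusted p = 0.441 with an estimated correlation). The adjusted p was 0.0505 without low cryosurvival library 2 (median -0.20), 0.144 without low library 1, 0.136 without high library 3 and 0.0562 with the length index. ECI2, an isomerase of this pathway, was at 33.0 ± 4.58 against 56.8 ± 7.12 CPM (limma adjusted p = 0.164, and 0.0235 with the length index). ACAA1 was at 239 ± 60.6 against 238 ± 6.13 CPM, and 0 members passed adjusted over the list alone. The 5 lists of hypoblast, junction, oxidative stress, chromatin and beta-oxidation genes each lost their call in at least 1 fit with a library left out, and the heat shock, inflammatory and apoptosis lists were called in all 6. Without high cryosurvival library 3 the count of called lists fell from 8 to 4.

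The other lists were not called by camera with all 6 libraries. Extracellular matrix genes had a median log2 difference of 0.21 (adjusted p = 0.0995), with MMP14, a membrane-bound collagenase, at 55.9 ± 18.2 CPM in low and 23.9 ± 3.94 CPM in high cryosurvival embryos. In low cryosurvival library 2 the matrix median was -0.22 against the high mean. Without this library it was 0.41 and the list was called higher in low (camera adjusted p = 0.00566; adjusted p = 0.464 with an estimated correlation). Imprinted genes had a median log2 difference of -0.26 (adjusted p = 0.0995), with GNAS at 341 ± 20.9 against 442 ± 35.7 CPM. Without low cryosurvival library 3 the median was -0.11 (adjusted p = 0.245). Genes of IGF, FGF and WNT signalling had a median log2 difference of 0.08 (adjusted p = 0.106) and 4 members that passed limma adjusted over the list alone, each higher in low. Its median was -0.15 in low cryosurvival library 2 against the high mean. Without this library it was 0.19 and the list was called higher in low (camera adjusted p = 0.0432; adjusted p = 0.593 with an estimated correlation). The matrix and signalling lists were also called higher without high cryosurvival library 1 (camera adjusted p = 0.0255 for both), when the signalling median was 0.23. The matrix median was 0.05 without low library 3, 0.10 without low library 1 and 0.13 without high library 2 (adjusted p = 0.245, 0.334 and 0.262). The signalling median was 0.03 without high library 3 (adjusted p = 0.3), and 0.13 and 0.14 without low library 3 and high library 2. The 4 signalling genes were FGFR4, WNT11 and, named after their values were seen, DKK3 and CCND1. FGFR4 was at 270 ± 35.0 against 160 ± 17.9 CPM and WNT11 at 1.77 ± 0.380 against 0.586 ± 0.270 CPM. The cell cycle list had a median log2 difference of -0.06 (adjusted p = 0.374). CDK6, a G1 kinase, was at 8.07 ± 1.90 against 3.00 ± 0.821 CPM and was its single member to pass limma adjusted over the list alone. Median log2 differences were -0.03 for lipid droplets and lipid synthesis (adjusted p = 0.677), -0.04 for cholesterol synthesis (0.889) and -0.01 for glycolysis (0.889). They were -0.04 for water channels and ion transport of the blastocoel (0.889), -0.06 for oxidative phosphorylation (0.374) and 0.04 for cytosolic ribosomal proteins (0.701). Among the lists of this paragraph limma called 0 members over all genes, and PFKP of glycolysis (higher in low) and NAP1L5 of the imprinted genes (lower) each passed adjusted over the list alone. Both were named after their values were seen. FASN, the fatty acid synthase, was at 2207 ± 868 CPM in low and 2452 ± 330 CPM in high cryosurvival embryos. Its log2 difference was -0.23, and 0.14 without low cryosurvival library 2, and it was called in neither fit.

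**Figure D2:**
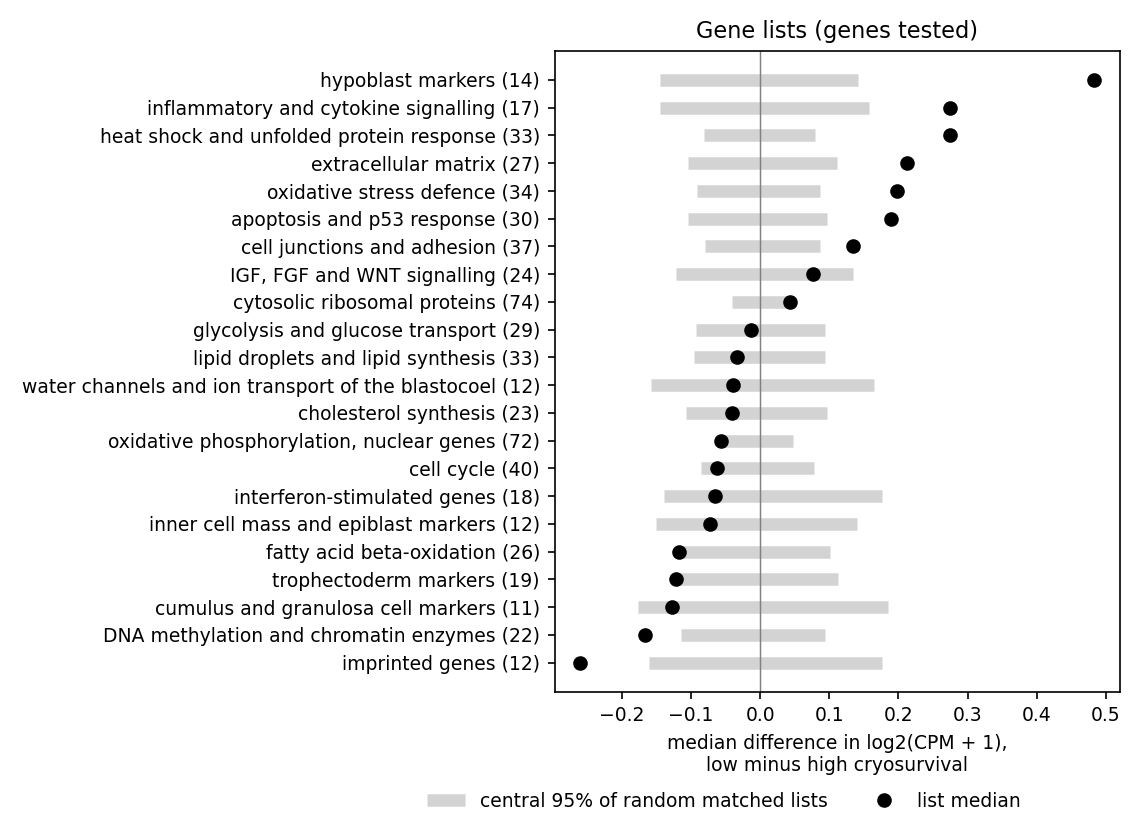
Black points are the median differences in log2(CPM + 1), low minus high cryosurvival, of the 22 lists tested, with the number of measured genes in parentheses; grey bars are the central 95% of 10000 random lists matched on size and mean expression. Hypoblast markers (0.48) and the inflammatory and heat shock lists (0.27 each) lie to the right of their bars, and imprinted genes (-0.26) and chromatin enzymes (-0.17) to the left.

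Low cryosurvival library 2 stood apart from the other libraries. Of 7947 genes with a mean above 5 CPM, 1036 in this library (13%) differed by more than 2-fold from the other 2 libraries of its group, 624 below and 412 above. This compared with 168 in low cryosurvival library 1, 55 in library 3 and 2 to 9 in the high cryosurvival libraries. Genes with long messenger RNAs had a median log2 deviation of -0.998 in this library from the other 2 low libraries, and genes with short messenger RNAs one of 1.005. The length index was -1.63 in low cryosurvival library 2, 0.65 and 0.23 in low libraries 1 and 3, and between -0.19 and 0.08 in the high libraries. The median log2 differences of the ribosomal and oxidative phosphorylation lists moved with this library. Without it they were -0.27 and -0.37, and both lists were called lower in low (camera adjusted p = 7.04e-11 and 3.43e-14; adjusted p = 0.515 and 0.464 with an estimated correlation). The ribosomal list was called higher in low without low library 1 (camera adjusted p = 0.00167) and without low library 3 (0.0204), both at the preset correlation. The correlation was not estimated in these fits. With all libraries the estimate for this list was 0.952 (camera adjusted p = 0.934).

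**Figure D3:**
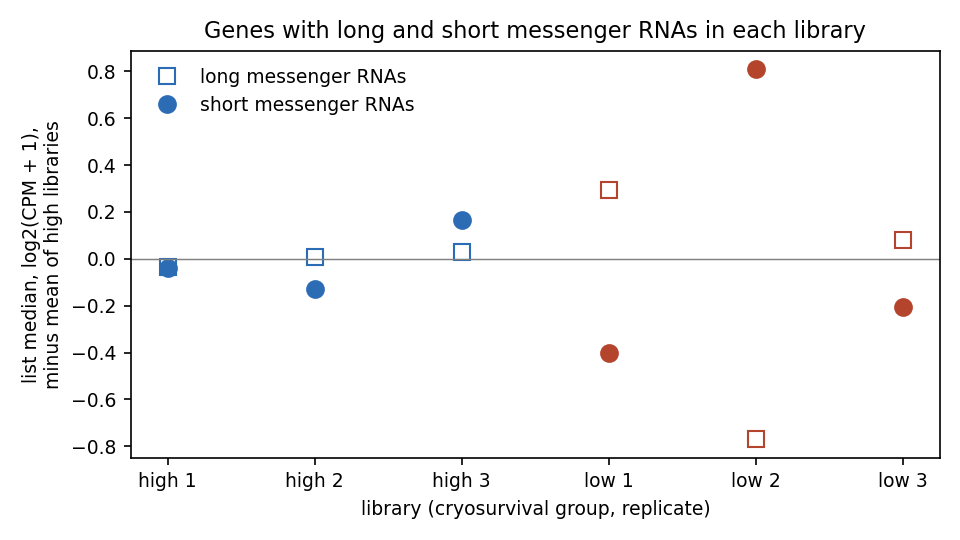
Each symbol is the median log2(CPM + 1) of genes with long (open squares) or short (filled circles) messenger RNAs in 1 library, minus the mean of the 3 high cryosurvival libraries, with high cryosurvival in blue and low in red. Low library 2 has the lowest value for long and the highest for short messenger RNAs.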

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

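The settings that weight libraries, use voom, an intensity trend, a pseudocount of 0.5, library medians, the length index, Fisher's exact test on the deposited calls or an estimated correlation in another fit were chosen only after the result was seen. For single genes, limma's count of 0 became 17 at an adjusted p of 0.10, 7 without the 25% of genes lowest in expression, 7 with a pseudocount of 0.1, 10 with 0.5, 7 with libraries centred on their medians, 1092 with the length index, 2007 with voom and a weight per library, and 4366 with limma and a weight per library. Low cryosurvival library 2 had a weight of 0.098 in voom and 0.0592 in limma, which gave low library 3 a weight of 14.6. Leaving out each library gave 0 to 1300 genes, the 1300 without low cryosurvival library 2. The 8 called lists became 3 at an adjusted p of 0.01, 4 without these genes, 0 with an estimated correlation (0 also with the length index or without low cryosurvival library 2), 1 with Fisher's exact test and 4 to 11 with each library left out. The 114 genes of the authors' deposited table became 47 at an adjusted p of 0.01, 177 at 0.10 and 53 without these genes; 71.8% to 78.7% of these calls were higher in low. Of the 83 genes taken by the rule for named genes as applied, 14 changed sign without low cryosurvival library 2, with 0 called in either fit. IFITM3 turned from 0.01 to -0.32 on the log2 scale with limma and a weight per library. Apart from fewer genes, libraries or calls, the cause was not tested. For named genes and called lists, 1697 values across the settings stayed on their side of the threshold, 210 passed it and 57 no longer did. The replicate block gave 0 genes and 9 lists. Deviations of same-numbered libraries from their group means correlated at 0.12, -0.26 and -0.31. Low cryosurvival library 2 moves the mean of its group, so these correlations cannot tell whether the numbers pair the libraries. The count tests planned for raw counts, Bonferroni on the deposited p-values and a match by identifier were not run.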

Other observations

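The tests with the length index, the thinning of reads as given here, the side on which low cryosurvival library 2 lies, the stress lists in that library, the cell lineage shares and the splits for called genes were chosen only after the result was seen. The genes named in this paragraph were also chosen after their values were seen. In the authors' deposited table, CRYAB and HSPB8, which encode small heat shock proteins, the endoplasmic reticulum chaperone gene HYOU1 and the phosphatase subunit gene PPP1R15A were higher in low cryosurvival embryos (adjusted p = 0.002, 0.048, 0.044 and 0.041). Limma without covariate did not call them (adjusted p = 0.142, 0.241, 0.237 and 0.142). HYOU1 was at 689 ± 173 CPM in low and 394 ± 31.1 CPM in high cryosurvival embryos, and PPP1R15A at 81.1 ± 5.54 against 49.2 ± 3.97 CPM (SD, n = 3 each). PTPRN, a protein of secretory granules, was at 131 ± 22.2 against 39.1 ± 9.65 CPM, the stress-responsive kinase PLK2 at 78.9 ± 5.29 against 30.7 ± 2.42 CPM, and the chemokine CXCL16 at 30.3 ± 2.15 against 10.7 ± 2.77 CPM. The transcription factors FOSL1, MAFF and ETS1 were at 28.8 ± 11.4 against 10.6 ± 1.82, 30.6 ± 7.27 against 12.5 ± 1.27 and 19.3 ± 7.6 against 6.57 ± 0.280 CPM. GCM1, a transcription factor of the placenta, went the other way, at 9.15 ± 0.694 CPM in low and 17.0 ± 2.58 CPM in high cryosurvival embryos.

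Limma with the length index called genes outside the authors' deposited list, among them PHLDB2 (log2 difference 1.04, adjusted p = 0.00857) and RSPO3 (0.82, 0.0136) higher in low, and CNTNAP1 (-0.97, 0.019), FCGR2B (-0.81, 0.0125) and HAUS5 (-0.83, 0.0125) lower. In the same model 2 of the 8 called lists, oxidative stress and beta-oxidation, lost their call (camera adjusted p = 0.0846 and 0.0562). The oxidative stress median fell from 0.198 to 0.111, while that of beta-oxidation stayed about as large (-0.117 and -0.108). There were 2 other lists that gained a call. The nuclear genes of oxidative phosphorylation were lower in low cryosurvival embryos as a list (camera adjusted p = 5.28e-05, with 2 of 72 members called and 0 adjusted over the list alone), and extracellular matrix genes were higher (0.0214, with 7 of 27 members called higher and 1 lower). With an estimated correlation neither list was called in this model (adjusted p = 0.359 for both). In the fits without the index, the oxidative phosphorylation median turned to 0.121 without low library 1 and to 0.051 without low library 3. Camera called the list in neither of these (adjusted p = 0.103 and 0.6). Of the 33 lipid droplet and lipid synthesis genes the model called 1 higher and 4 lower in low, and the list was not called (camera adjusted p = 0.864). ACSL6, a fatty acid activating enzyme, was at 253 ± 68.5 CPM in low and 404 ± 24.4 CPM in high cryosurvival embryos, and the lipid droplet coat gene PLIN2 at 113 ± 5.31 against 82.0 ± 6.36 CPM (limma adjusted p = 0.0136 and 0.0293 with the length index). The lower ones also included DGAT1, FABP3 and another droplet coat gene, PLIN1, at 0.993 ± 0.405 against 1.83 ± 0.280 CPM (adjusted p = 0.0263). The genes of this paragraph were chosen after their values were seen.

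Low cryosurvival library 2 stood apart from the other 5 libraries. Thinning the reads of low library 1 to the depth of library 2 took its genes beyond 2-fold from the other 2 low libraries from 168 to 167, a change of -0.1% of the 1036 of library 2, and moved the medians of long and short messenger RNAs by -0.003 each, which argues against depth. The cumulus and granulosa list deviated by -0.16, inside the range of random lists (-0.496 to 0.412), and so gave no sign of these cells as the source. This short list cannot exclude a small share of them. Of its 2 most abundant members, CYP11A1 was highest in library 2 (239 against 186 and 111 CPM in low libraries 1 and 3). HSD3B1 was not (247 against 311 and 245 CPM). The list of long messenger RNAs deviated by -0.998 and that of short ones by 1.005, outside the central 95% of random lists on opposite sides, so RNA or library quality that acts through transcript length is a candidate explanation, while the labels state an RNA integrity number of at least 7.7 for every sample. A biological difference of the embryos in this library stays open and untested.

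More genes were called when low cryosurvival library 2 was left out. In 47.3% of the 1300 genes called without it, library 2 lay on the other side of the high cryosurvival mean from libraries 1 and 3, against 53.8% of all genes, which leaves open how far its axis enters these calls. The long list differed by 0.343 and the short list by -0.31 between low libraries 1 and 3 and the high libraries, so a length trend may be part of the calls made without library 2. Of the 1300 genes, 800 were also called in the same direction with the length index. That model takes most of the deviation of library 2 out of the spread. Both fits share the remaining libraries, so this overlap is not independent support.

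The heat shock, inflammatory and apoptosis lists were higher in low cryosurvival embryos. In the model with the length index all 3 lists were still called at the preset correlation (largest camera adjusted p = 0.0192). With an estimated correlation none was (camera adjusted p = 0.359 for each). The p-values at the preset correlation do not measure the spread between libraries, so these calls cannot decide whether the length trend is the cause. With the index the heat shock, inflammatory and apoptosis medians were 0.261, 0.331 and 0.137, against 0.274, 0.274 and 0.19 without it. The slope behind this adjustment is set mainly by low library 2. In low library 2 alone, the medians above the high mean were 0.48 for inflammatory, 0.257 for apoptosis and 0.213 for heat shock genes, at the 99.95th, 98.4th and 87.6th percentiles of random lists; the first 2 go against the axis of that library, but on 1 library it cannot be told apart from a group difference. Hypoblast markers (0.483) and trophectoderm markers (-0.121) lay outside random lists on opposite sides, so a changed share of cell types may contribute. The trophectoderm median was only just outside (1.98th percentile). Camera did not call that list (adjusted p = 0.214, and 0.87 with an estimated correlation). In low library 2 alone both lists lay inside random lists (0.101 and 0.129), and inner cell mass markers lay below them (-0.461). The trophectoderm median was 0.055 without low library 3. A difference of the embryos that goes with cryosurvival stays open and untested.

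The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes called by limma without covariate, 10 of 10 splits gave as many as the real count of 0, the highest other being 0. With a real count of 0 this outcome was fixed in advance and decides nothing. For called lists it was 3 of 10 splits, with 8 in the real split, 9 in the highest other and 2 in the lowest. Every split other than the real one thus also gave called lists. For genes at an unadjusted p below 0.05 it was 2 of 10, with 1142 in the real split and 1319 in the split of high libraries 1 and 3 with low library 2 against the rest, which follows the length index. With the length index it was 1 of 10, with 1092 genes in the real split and 0 in the highest other.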
